A study of Mus musculus with 22 samples.

How the data were processed

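RNA was measured in 22 libraries of donor T cells, with 1 library per sample and 8 groups of cell type, tissue and treatment. Per the labels' protocols, spleen and bone marrow cells of wild-type C57BL/6 mice were given to lethally irradiated wild-type BALB/c recipients. The recipients were treated with control IgG or a monoclonal antibody against IL-2 (anti-IL-2), and donor CD4 and CD8 T cells were sorted from spleen and colon (called gut here) on day 7. Libraries were made with a stranded mRNA kit. The title of the series also names recipients that lack PD-L1, and such recipients were not analysed here, since each of the 22 samples was labelled as wild type.

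The deposited table holds raw read counts per gene symbol, whole numbers of at least 0. Per the submitters' processing notes, reads were aligned with TopHat2 and counted with HTSeq 0.9.1 on genome build mm10. The notes do not state the annotation, the strand setting or the filters. The table holds 24091 gene names, of which 23509 (97.6%) matched a symbol of GENCODE release M21 for the same build, and coordinates were taken from that annotation. Total counts per library ran from 14628806 to 24518362. A count covers counting error only, because reads without molecular identifiers are not independent molecules.

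Groups were taken from the source name and the sample characteristics. For the 5 CD8 IgG libraries the description field names the other tissue, and the tissue in the source name was used. Each spleen group and each gut anti-IL-2 group held 3 libraries, and each gut IgG group held 2, because batch 181201 has no gut IgG library. The 3 batches are named 181201, 181212 and 190306 in the labels. The labels do not say whether libraries of a batch came from the same animals or from pooled animals. The p values therefore measure the spread between these libraries and not between recipients.

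Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr on the group, which left 12841 genes, and library sizes were scaled by TMM. All 22 libraries entered a single quasi-likelihood model (robust) with 8 groups and batch as a fixed term, which has 12 residual degrees of freedom. Contrasts compared anti-IL-2 with IgG in each population, gut with spleen in each cell type and treatment, the treatment effects between tissues and between cell types (interactions), and CD4 with CD8 cells. The p values were adjusted by Benjamini-Hochberg over all genes tested within a contrast, with a threshold of 0.05, and log2 fold changes are given with their standard error (SE). CPM is the count scaled by library size, and log2 CPM was computed in edgeR with a prior count of 2.

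The contrasts, the gene lists, the rule for named genes and the alternatives called fixed here were set before the data were examined. The 33 gene lists covered IL-2 and STAT5 targets, cytokine receptors, T cell states, metabolism, stress and interferon responses, and markers of other cell types. Of these, 32 had at least 2 members tested. Lists were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a contrast. Of the list members, 10 symbols were absent from the table. In every list, counts of members past 0.05 are given over all genes tested and adjusted over the list alone.

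Genes were named in the text by these criteria. For each treatment and each gut and spleen contrast, the 12 largest changes per direction were taken among genes past 0.05 with a mean log2 CPM of at least 2 and the same direction in every batch holding both groups. Clone names and immunoglobulin or T cell receptor segments were left out. The members with the smallest p of each called list, the 10 genes with the smallest p where fewer than 5 genes passed, and Il2, Il2ra, Il2rb, Cish, Socs1, Socs2, Bcl2, Foxp3, Ifng, Csf2, Il10, Pdcd1, Tcf7, Tox, Gzmb and Mki67 were added. Interactions and the comparison of cell types gave 5 genes per direction.

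After the model of all batches had been seen, the labelled treatment difference was compared between batches, by correlations across genes of mean log2 CPM of at least 2 and by a model in which batch 190306 had its own treatment effect. In that model each group of batch 190306 held 1 library, so the spread came from batches 181201 and 181212 alone. Because batch 190306 differed from the others, the treatment contrasts were fitted again without it. That fit, of batches 181201 and 181212, was therefore chosen after seeing the data. It held 14 libraries and 13073 genes and had 5 residual degrees of freedom, and each gut IgG group then held 1 library, whose spread was taken to be that of the other groups. In the gut treatment contrasts of that fit only batch 181212 holds both groups. The condition of the same direction for named genes therefore covers 1 batch there. No library was given another label.

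The fixed alternatives were DESeq2 1.42.0, RLE factors, no filter, a stricter filter (CPM of at least 1 in at least 5 libraries), no batch term, limma voom with sample weights, batch 181201 left out, a block of batch by treatment, libraries of the same cell type or the same tissue only, the tissue in the description field for the CD8 IgG libraries, an estimated correlation for the list of IL-2 and STAT5 targets, and each library left out in turn. The block groups libraries by the batch and treatment of the labels. Deviations from the group means correlated at 0.479 to 0.832 in 31 pairs of libraries of the same batch and labelled treatment. In 40 pairs of the same batch with different treatments they correlated at -0.0696 to 0.217. The opposite difference of batch 190306 enters these deviations, so they cannot show a pairing of libraries beyond it. Alternatives for the fit without batch 190306 were chosen after seeing the data. The procedure was tested on simulated counts with 50 genes changed at each of 4 fold sizes. At a 2-fold change it recovered 82% of the changed genes for the spleen CD4 treatment contrast in all batches (12481 genes) and 94% in batches 181201 and 181212 (12499 genes). For gut against spleen in CD4 anti-IL-2 cells it recovered 84% (12494 genes). The simulated libraries were independent and had no batch effect and no opposite treatment effect in batch 190306. These shares may therefore not hold for the real libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.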

Results

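The 22 libraries held donor T cells taken from transplant recipients 7 days after transfer, from 2 cell types (CD4 and CD8), 2 tissues (spleen and gut) and 2 treatments (IgG and anti-IL-2). Each spleen group and each gut anti-IL-2 group had n = 3 libraries, with 1 in each of the 3 batches, and each gut IgG group had n = 2, from batches 181212 and 190306. Total counts ran from 14628806 to 24518362 per library, and 14042 to 15411 gene names had a count. Actb, cytoskeletal actin, was the most abundant gene in each of the 22 libraries and took from 0.553% to 1.33% of the counts. The main axis of variation across libraries, with 31.3% of the variance, followed cell type. The next axis, with 23.0%, followed tissue. The third, with 16.6%, and the fourth, with 6.36%, followed combinations of batch and treatment, which accounted for 83.8% and 92.1% of their spread.

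The series asks how neutralising IL-2 affects the IL-2 and STAT5 pathway in donor T cells, so transcripts induced by that pathway were examined first. In batches 181201 and 181212, libraries labelled anti-IL-2 held less Il2ra (the high-affinity IL-2 receptor chain) than IgG libraries in each of the 4 populations. The log2 fold change was -2.01 ± 0.12 (SE) in spleen CD4 cells, -1.78 ± 0.12 in spleen CD8 cells, -1.08 ± 0.14 in gut CD4 cells and -1.24 ± 0.14 in gut CD8 cells. Socs2, a STAT5-induced feedback inhibitor of cytokine signalling, fell as well, with log2 fold changes of -3.15 ± 0.18, -3.89 ± 0.24, -2.03 ± 0.17 and -2.93 ± 0.19 in the same order. Cish, another such inhibitor, was at -1.51 and -1.69 in spleen CD4 and CD8 cells and at -0.59 and -0.63 in the gut. In batch 190306 the difference ran the other way, with Il2ra higher in the libraries labelled anti-IL-2 by 1.76, 1.83, 1.56 and 1.64 in log2 CPM. Socs2 was higher by 2.65, 2.75, 2.70 and 4.64. A single batch holds 1 library per group, so these last values have no error of their own. The test that follows takes its spread from the other batches. By the edgeR model with a separate treatment effect for batch 190306, the treatment difference in Il2ra differed between batches with adjusted p = 9.09e-07, 2.29e-06, 3.79e-05 and 3.08e-05.

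**Figure D1:**
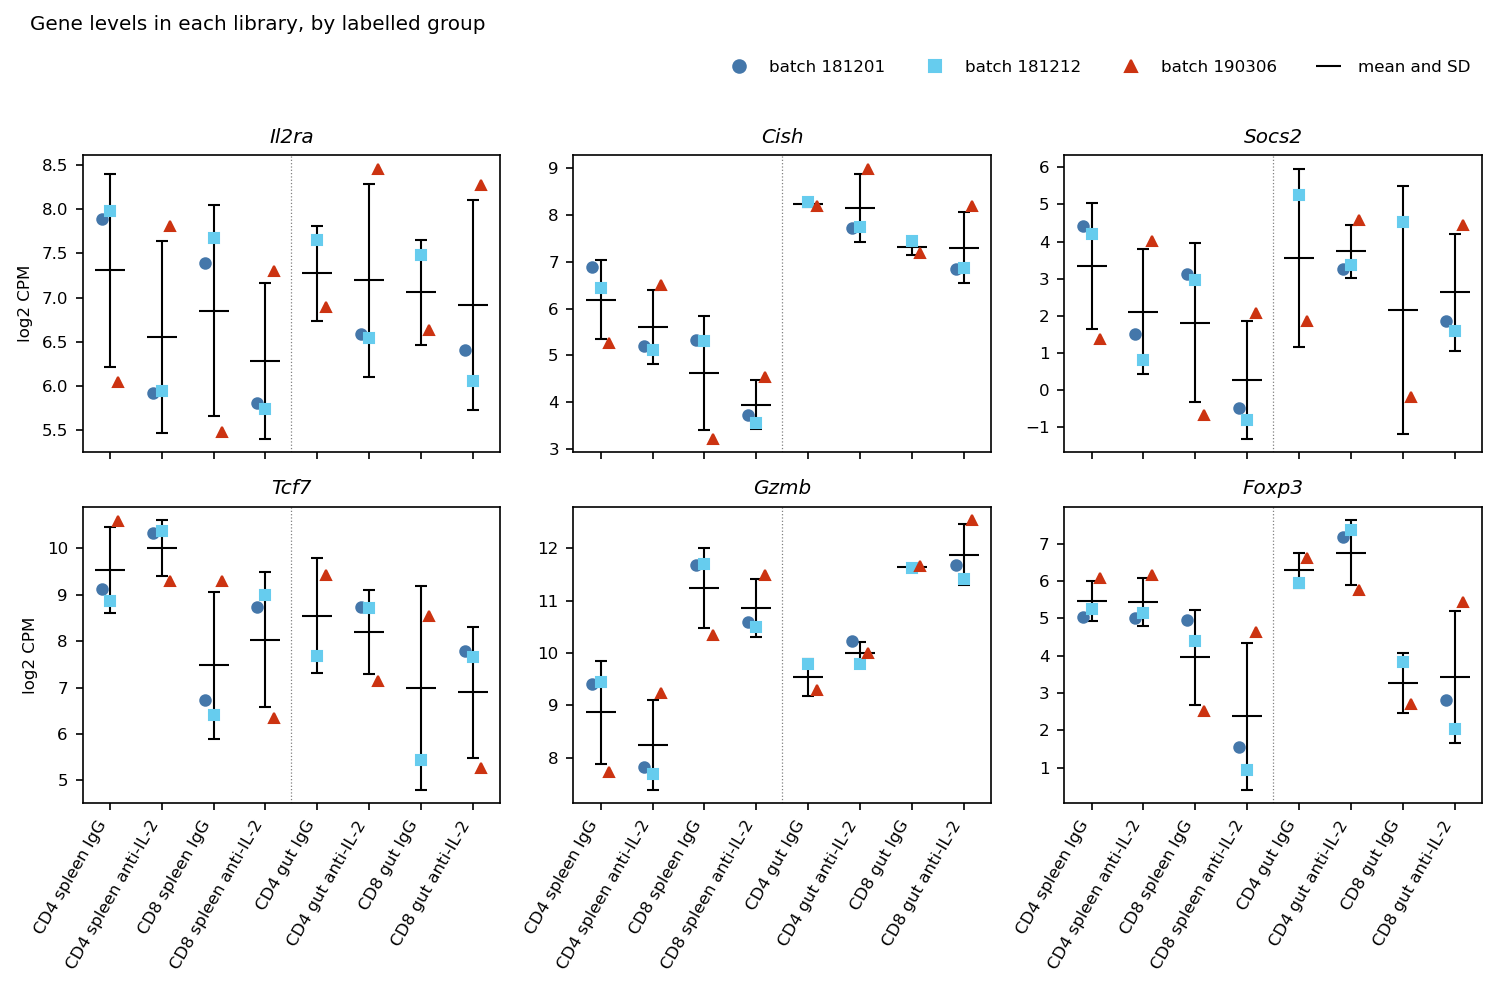
Levels of 6 genes in each of the 22 libraries as log2 CPM (vertical axis), by labelled group (horizontal axis), with points coloured by batch and bars for the group mean and SD. In batch 190306 the Il2ra, Socs2 and Tcf7 points lie on the opposite side of their group mean from the points of batches 181201 and 181212 in the spleen groups.

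With all 3 batches in a single edgeR model, no gene passed the threshold for anti-IL-2 against IgG in any of the 4 populations (0 of 12841 genes in each). At an unadjusted p under 0.05 there were 282 genes in spleen CD4 cells, 148 in spleen CD8 cells, 750 in gut CD4 cells and 953 in gut CD8 cells. DESeq2 called 0, 0, 8 and 18 genes, and limma voom 0, 0, 0 and 1. The smallest p belonged to Ppp1r10 in spleen CD4 cells (log2 fold change -0.25 ± 0.06), Slc25a20 in spleen CD8 cells (0.32 ± 0.08), Zfp866 in gut CD4 cells (0.55 ± 0.08, adjusted p = 0.0663) and Snord57 in gut CD8 cells (-1.42 ± 0.25, adjusted p = 0.346). The next smallest in spleen CD4 cells were B3galt5, Ubash3b, Cdk5rap1 and Rps27. In spleen CD8 cells they were Cdk5rap1, Dennd1a, Zfp955b and Tcea2. In gut CD4 cells they were Zfp397, Ireb2, Rlim and Cnep1r1, and in gut CD8 cells Trim69, Snord2, Rpl10 and Ciart. The list of IL-2 and STAT5 targets had a mean log2 fold change of -0.07, -0.05, -0.0042 and -0.07 in the same order. Its adjusted p was 0.168, 0.996, 0.556 and 0.282 (camera). Its mean and median differed in sign in spleen CD8 cells (median 0.01) and gut CD8 cells (median 0.03), and 0 of its 49 members passed over all genes or adjusted over the list alone. Camera with the preset correlation called 9, 6, 3 and 7 of 32 lists, among them proliferation, follicular helper genes and stress genes. With an estimated correlation it called 0 in each population.

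The labelled treatment difference was opposite in batch 190306 for most genes that changed in the other batches. Across genes, which are not independent replicates, the correlation between the difference in batch 190306 and that in batches 181201 and 181212 was r = -0.751 in spleen CD4 cells, -0.729 in spleen CD8 cells, -0.527 in gut CD4 cells and -0.490 in gut CD8 cells. The 8 correlations between batches 181201 and 181212, taken over all pairs of populations, ran from 0.278 to 0.635, and the 24 that set batch 190306 against them ran from -0.731 to -0.369. Of the genes called without batch 190306, 95.5% in spleen CD4, 97.3% in spleen CD8, 81.0% in gut CD4 and 76.9% in gut CD8 had the opposite sign in that batch. A test of the batch by treatment difference called 3123, 2070, 1921 and 1666 genes. In that test each group of batch 190306 held 1 library, so the p values measure no spread within that batch. The libraries of batch 190306 were kept under their labels. The treatment results that follow come from batches 181201 and 181212 and were chosen after seeing this difference, and each holds for those batches only.

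**Figure D2:**
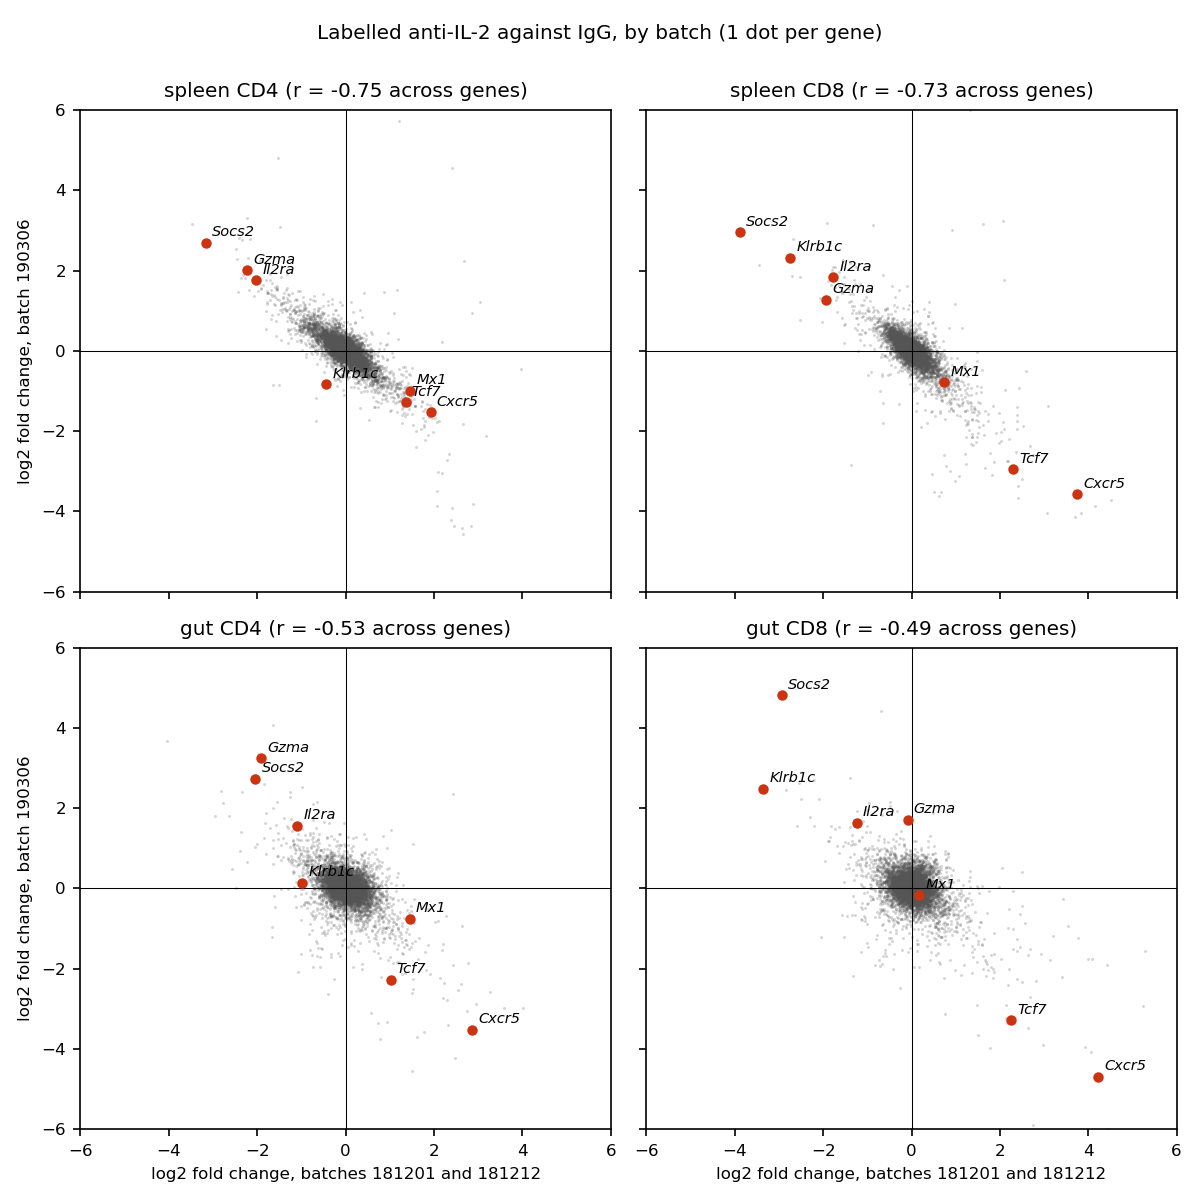
Log2 fold change of libraries labelled anti-IL-2 over IgG in batch 190306 (vertical axis) against batches 181201 and 181212 (horizontal axis), with 1 dot per gene and 7 genes named. The correlation across genes is -0.751 in spleen CD4, -0.729 in spleen CD8, -0.527 in gut CD4 and -0.490 in gut CD8 cells, and 1, 2, 6 and 8 genes lie outside the axes in the same order.

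In spleen CD4 cells of batches 181201 and 181212, anti-IL-2 libraries (n = 2 against 2) held less RNA for cytotoxicity genes and more for follicular helper, interferon response and memory genes. The granule proteases Gzma and Gzmb had log2 fold changes of -2.23 ± 0.19 and -1.67 ± 0.10, and Csf2, which encodes GM-CSF, of -2.26 ± 0.23. Deptor, which encodes an inhibitor of mTOR, was at -3.47 ± 0.21, and Itga1, an integrin chain that binds collagen, was at -2.35 ± 0.18. Higher transcripts included Eomes, a T-box transcription factor (3.19 ± 0.50), Slc40a1, an iron exporter also made by macrophages (2.84 ± 0.28), Dapl1 (2.30 ± 0.18), and Tcf7, the transcription factor TCF1 of naive and memory cells (1.37 ± 0.12). Bcl6, the master regulator of follicular helper cells, rose by 1.47 ± 0.11. Of 13 follicular helper genes 11 rose (11 adjusted over the list alone, adjusted p = 3.6e-18, and 0.0416 with an estimated correlation). Of the 35 type I interferon response genes, 25 rose, and 30 did adjusted over the list alone (adjusted p = 8.23e-22, and 0.00284 estimated), among them Mx1 (1.47 ± 0.09) and Oas1a (1.14 ± 0.12). In the cytotoxicity list 15 of 19 genes fell and 2 rose (16 and 2 adjusted over the list alone, adjusted p = 3.12e-17, and 0.0337 estimated). Klrk1, which encodes the receptor NKG2D, was at -1.66 ± 0.11. In the list of naive and memory genes 10 of 18 rose and 1 fell (the same counts adjusted over the list alone, adjusted p = 8.05e-08, and 0.0416 estimated). They included Ccr7, a lymph node homing receptor (1.55 ± 0.16). The proliferation list fell in 35 of 40 members, 38 adjusted over the list alone, with Mki67 at -0.84 ± 0.07 (adjusted p = 1.53e-31, and adjusted p = 0.106 with an estimated correlation, where the call was lost).

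The list of IL-2 and STAT5 targets moved in both directions in spleen CD4 cells. Of 49 members, 17 fell and 7 rose (17 and 9 adjusted over the list alone), with a mean of -0.18 (adjusted p = 0.000244, and adjusted p = 0.254 with an estimated correlation). Beside Socs2, Cish, Gzmb and Il2ra, the IL-18 receptor chain Il18r1 fell (-0.77 ± 0.05), while Il2rb, the shared receptor chain for IL-2 and IL-15, changed by -0.49 ± 0.08. Th2 genes fell in 6 of 10 members (7 adjusted over the list alone, adjusted p = 0.0011, and 0.0675 estimated), and 1 rose. Il17rb, a receptor for IL-25, was at -2.30 ± 0.28. Th1 and inflammatory genes fell in 9 and rose in 6 of 21 (10 and 7 adjusted over the list alone, adjusted p = 0.0385, and 0.175 estimated). Tissue residence and gut homing genes fell in 5 of 16 and rose in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.000204, and 0.0442 estimated). Anergy genes rose in 6 of 15 and fell in 1 (7 and 3 adjusted over the list alone, adjusted p = 0.0031, and 0.254 estimated). Cholesterol synthesis genes fell in 8 of 23 (8 adjusted over the list alone, adjusted p = 0.00851, and 0.522 estimated). Foxp3 (-0.08 ± 0.23), Ifng (-0.49 ± 0.48), Il2 (0.74 ± 0.28), Il10 (0.29 ± 0.25), Bcl2 (0.04 ± 0.10), Socs1 (-0.04 ± 0.10) and Pdcd1 (0.10 ± 0.06) did not pass, and Tox was at 0.92 ± 0.17. Markers of macrophages were higher too (2 of 16 members, and 2 adjusted over the list alone, adjusted p = 0.00126, and 0.657 estimated), with Cd68 at 0.86 ± 0.13. Their mean difference was 2.01 in batch 181201 (15 of 16 higher), 0.90 in batch 181212 (13 higher) and -2.18 in batch 190306 (13 lower). Dendritic cell markers (3 of 7 higher and 1 lower, 4 and 1 adjusted over the list alone, adjusted p = 0.216) and erythroid markers (2 of 6 higher, 3 adjusted over the list alone, adjusted p = 0.216) did not pass as lists. Their mean differences were 1.51, 0.90 and -1.26, and 2.74, 0.35 and 0.54, in the same order of batches. RNA from such cells was not separated from changes in T cells. Cd8a, at 1.42 ± 1.05 CPM (SD, n = 11) in CD4 cells of all batches, rose by 2.86 ± 0.57. In all, 1281 genes rose and 1346 fell by edgeR, and 1562 passed without CD4 spleen anti-IL-2 replicate 1. The same lists ran the other way in batch 190306, where the mean difference was -1.05 for follicular helper genes, -0.77 for interferon response genes and 0.57 for cytotoxicity genes. Stress and immediate early genes went in opposite directions in the 2 pooled batches, with a mean difference of -0.64 in batch 181201 (22 of 25 lower) and 1.20 in batch 181212 (22 of 25 higher), so the stress level differed between the treatment libraries within a batch.

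Spleen CD8 cells of batches 181201 and 181212 (n = 2 against 2) showed higher RNA of naive and memory, follicular helper and interferon response genes in anti-IL-2 libraries. Cxcr5, the homing receptor for B cell follicles, rose by 3.74 ± 0.30 and Ccr6, a mucosal homing receptor, by 3.69 ± 0.22. Tcf7 rose by 2.30 ± 0.12 and Id3, an inhibitor of E proteins, by 2.48 ± 0.16. Galnt9 (4.49 ± 0.83) and Sostdc1 (4.15 ± 0.65) rose as well. Lower transcripts included Socs2, Foxp3, the transcription factor of regulatory T cells (-3.47 ± 0.33), and Klrb1c, which encodes the NK receptor NK1.1 (-2.75 ± 0.13), with Gzma at -1.95 ± 0.18 and Gzmb at -1.16 ± 0.10. Follicular helper genes rose in 11 of 13 members (12 adjusted over the list alone, adjusted p = 2.41e-26, and 0.0265 estimated). Interferon response genes rose in 24 of 35 (26 adjusted over the list alone, adjusted p = 3.95e-21, and 0.00314 estimated), and naive and memory genes rose in 8 of 18 with 1 lower (the same adjusted over the list alone, adjusted p = 2.06e-18, and 0.00667 estimated). The calls of other lists were lost with an estimated correlation. Proliferation genes fell in 31 of 40 (37 adjusted over the list alone, adjusted p = 1.94e-23, and adjusted p = 0.143 estimated), with Mki67 at -0.59 ± 0.07. Cytotoxicity genes fell in 8 of 19 and rose in 1 (10 and 2 adjusted over the list alone, adjusted p = 2.09e-06, and adjusted p = 0.14 estimated). In the list of IL-2 and STAT5 targets 10 of 49 fell and 9 rose (13 and 11 adjusted over the list alone), with a mean of -0.13 (adjusted p = 0.0449, and adjusted p = 0.671 estimated).

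Further lists passed in spleen CD8 cells. Anergy genes rose in 6 of 15 (7 adjusted over the list alone, adjusted p = 8.74e-05, and 0.143 estimated), with Nt5e, the ectonucleotidase CD73, at 1.07 ± 0.08. Inhibitory receptor genes rose in 7 of 20 and fell in 3 (the same adjusted over the list alone, adjusted p = 0.0449, and 0.671 estimated). Pdcd1, which encodes PD-1, was at 0.36 ± 0.06 and Cd244 at -1.12 ± 0.16. Th17 genes rose in 4 of 10 and fell in 1 (4 and 1 adjusted over the list alone, adjusted p = 0.000171, and 0.143 estimated). The members that rose included Ccr6 and Il21, a cytokine also made by follicular helper cells (1.53 ± 0.24). Th2 genes fell in 3 of 10 (3 adjusted over the list alone, adjusted p = 0.0289, and 0.143 estimated). The NK marker list passed through Klrb1c alone, 1 of 4 members (1 adjusted over the list alone, adjusted p = 2.22e-06, and 0.0726 estimated). Macrophage markers rose in 2 of 16 (2 adjusted over the list alone, adjusted p = 0.0449, and 0.726 estimated), with Cd68 at 0.90 ± 0.10, and had a mean difference of 0.89, 0.10 and -1.47 in batches 181201, 181212 and 190306. Tox (1.13 ± 0.17) and Bcl2, an inhibitor of apoptosis (0.66 ± 0.10), rose. Il2 (2.73 ± 0.91), Ifng (-0.06 ± 0.46), Csf2 (-0.33 ± 0.26), Il10 (0.53 ± 0.29), Socs1 (0.05 ± 0.11) and Il2rb (-0.25 ± 0.08) did not pass. In all, 792 genes rose and 795 fell by edgeR, and 693, 954, 669 and 697 passed without CD8 spleen IgG replicate 1, IgG replicate 2, anti-IL-2 replicate 1 and anti-IL-2 replicate 2. Of the 792 and 795 genes, 564 rose and 615 fell in spleen CD4 cells too. The 2 sets of calls cannot be taken as independent, because the labels do not say whether libraries of a batch came from the same animals. In batch 190306 the mean difference was -1.12 for follicular helper genes, -1.08 for naive and memory genes and 0.37 for cytotoxicity genes. Stress and immediate early genes were again at opposite signs, -0.42 in batch 181201 (20 of 25 lower) and 1.16 in batch 181212 (24 of 25 higher).

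**Figure D3:**
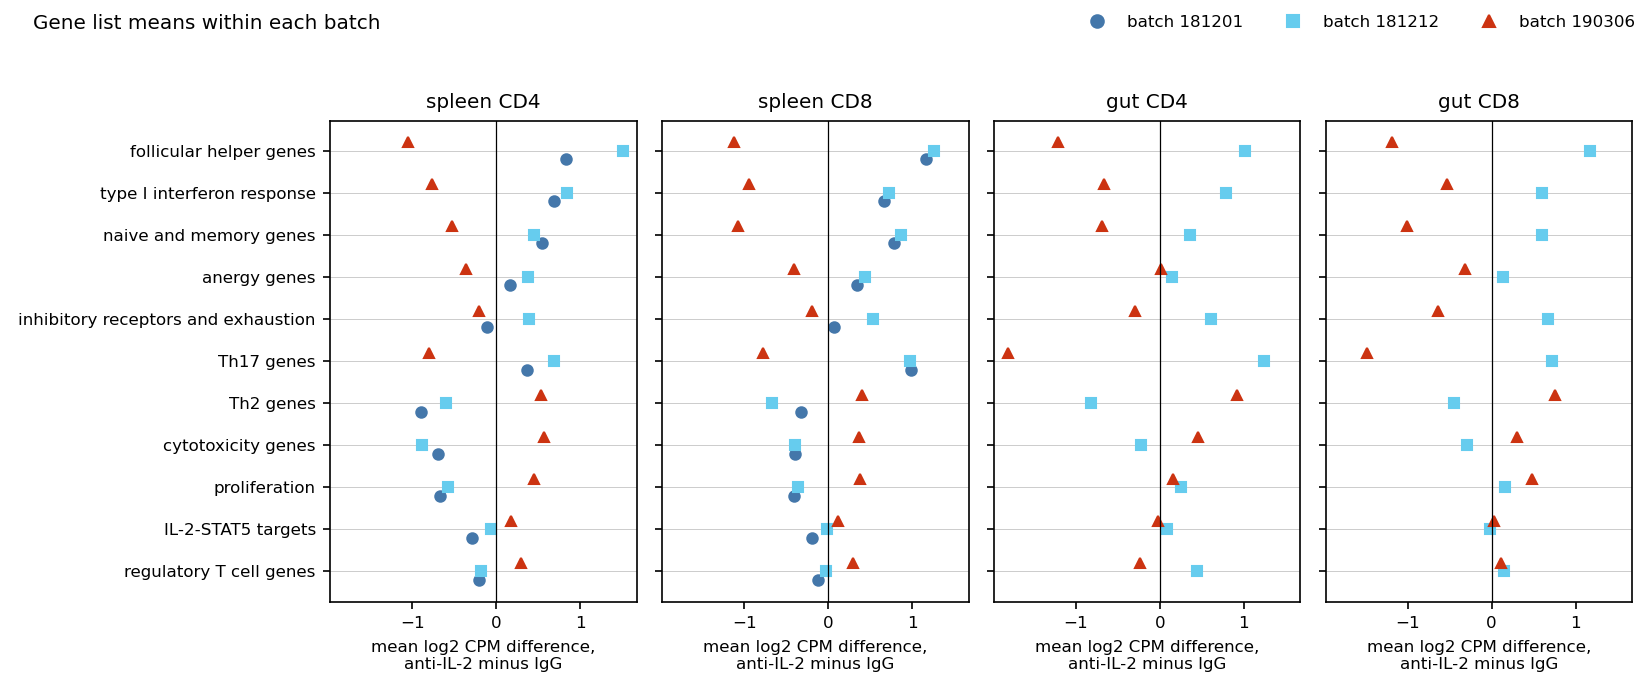
Mean difference in log2 CPM between libraries labelled anti-IL-2 and IgG (horizontal axis) over the members of 11 gene lists, with 1 point per batch in each of the 4 populations. Follicular helper genes are at 0.82 and 1.51 in spleen CD4 cells of batches 181201 and 181212 and at -1.05 in batch 190306.

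In gut CD4 cells of batches 181201 and 181212, 2 anti-IL-2 libraries were set against 1 IgG library, which was taken to vary like the other groups. The anti-IL-2 libraries held more RNA for interferon response genes, as in spleen, but Gzmb (0.16 ± 0.12) and Mki67 (0.08 ± 0.09) did not pass. Ccr6 rose by 2.95 ± 0.30, Cxcr5 by 2.86 ± 0.34, Eomes by 3.59 ± 0.76 and Foxp3 by 1.29 ± 0.27, with Il10, a regulatory cytokine, at 1.10 ± 0.27. Tcf7 was at 1.03 ± 0.15, Tox at 1.23 ± 0.23 and Il2 at 1.51 ± 0.36. Hspa1a, a heat shock protein (6.37 ± 1.36), and Anpep, an aminopeptidase also found on gut epithelium (4.35 ± 0.58), rose too. Among the largest rises were genes of other tissues, picked after their values were seen, with Fabp4 (9.61 ± 1.72) and Adipoq (8.05 ± 1.65) of fat cells and the pancreatic enzymes Cpb1 (8.83 ± 2.22) and Cela2a (8.28 ± 2.23). Deptor fell (-4.04 ± 0.19), with Il17rb at -2.81 ± 0.23 and Ifitm3, an antiviral membrane protein, at -2.63 ± 0.37. Interferon response genes rose in 19 of 35 members (26 adjusted over the list alone, adjusted p = 2.12e-16, and 0.00549 estimated). The calls of the other lists were lost with an estimated correlation. Follicular helper genes rose in 9 of 13 (11 adjusted over the list alone, adjusted p = 2.2e-13, and adjusted p = 0.113 estimated). Th17 genes rose in 4 of 10 and fell in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.000118, and adjusted p = 0.141 estimated), such as Il17a, which encodes IL-17A (1.69 ± 0.35). Inhibitory receptor genes rose in 8 of 20 (8 higher and 1 lower adjusted over the list alone, adjusted p = 0.000284, and adjusted p = 0.394 estimated), with Pdcd1 at 0.47 ± 0.08. Th2 genes fell in 4 of 10 (4 adjusted over the list alone, adjusted p = 0.000102, and adjusted p = 0.0971 estimated). Proliferation genes rose in 12 of 40 (13 higher and 1 lower adjusted over the list alone, adjusted p = 0.000502, and adjusted p = 0.674 estimated). Markers of colon epithelium rose in 5 of 26 and fell in 1 (10 and 1 adjusted over the list alone, adjusted p = 8.65e-05, and adjusted p = 0.394 estimated), with Krt20 at 3.94 ± 0.83. The list of IL-2 and STAT5 targets did not pass, with 10 of 49 higher and 5 lower (10 and 7 adjusted over the list alone, mean 0.02 but median -0.10 and test direction down, adjusted p = 0.26). In all, 790 genes rose and 743 fell by edgeR, and 872 genes passed without the batch term, 857 without CD4 gut anti-IL-2 replicate 1 and 635 without replicate 2. In batch 190306 the mean difference was -1.22 for follicular helper genes and -0.67 for interferon response genes. For the epithelium markers it was 1.40, with the same sign as the 1.46 of batch 181212. Macrophage, dendritic cell and stroma markers were at 1.23, 1.55 and 1.35 in batch 181212, and at -1.56, -0.88 and -0.29 in batch 190306. Their RNA was not separated from changes in T cells.

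Gut CD8 cells of batches 181201 and 181212 (n = 2 against 1) resembled gut CD4 cells in Ccr6 (4.45 ± 0.42), Cxcr5 (4.22 ± 0.58) and Tcf7 (2.24 ± 0.17), which rose in anti-IL-2 libraries. Klrb1c fell (-3.35 ± 0.15), as did Socs2, Ifitm3 (-2.84 ± 0.41) and Ifitm2 (-2.58 ± 0.41). Foxp3 (-1.40 ± 0.37, adjusted p = 0.0545), Gzmb (-0.14 ± 0.12) and Mki67 (0.05 ± 0.09) did not pass. Il2 was at 3.06 ± 0.89 and Tox at 1.36 ± 0.22. Interferon response genes rose in 12 of 35 members (20 adjusted over the list alone, adjusted p = 4.64e-09, and 0.0253 estimated), the 1 list called with an estimated correlation. Follicular helper genes rose in 7 of 13 and fell in 1 (the same adjusted over the list alone, adjusted p = 1.43e-09, and adjusted p = 0.161 estimated). Inhibitory receptor genes rose in 6 of 20 and fell in 1 (10 and 1 adjusted over the list alone, adjusted p = 1e-05, and adjusted p = 0.334 estimated). Proliferation genes rose in 13 of 40 (13 adjusted over the list alone, adjusted p = 2.36e-05, and adjusted p = 0.601 estimated). Th17 genes rose in 2 of 10 (2 adjusted over the list alone, adjusted p = 0.0243, and adjusted p = 0.41 estimated). Stress genes were called down with 2 of 25 lower (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.0243, and adjusted p = 0.753 estimated). Their mean, 0.10, was above 0, while their median was -0.43. Markers of other cells rose beside these lists, as did Dcn of fibroblasts (9.39 ± 1.15) and, picked after their values were seen, the pancreatic enzymes Cpb1 (9.32 ± 2.19) and Cela2a (8.75 ± 2.18). Colon epithelium markers rose in 10 of 26 (22 higher and 1 lower adjusted over the list alone, adjusted p = 1.25e-15, and adjusted p = 0.0691 estimated), such as Epcam (1.97 ± 0.27). Stroma markers rose in 5 of 14 (6 and 1 adjusted over the list alone, adjusted p = 3.51e-06, and adjusted p = 0.251 estimated). Macrophage markers rose in 2 of 16 (2 adjusted over the list alone, adjusted p = 0.000417, and adjusted p = 0.601 estimated). Dendritic cell markers rose in 2 of 7 (4 adjusted over the list alone, adjusted p = 0.00562, and adjusted p = 0.487 estimated), with Cd74 at 3.13 ± 0.64. The NK marker list fell through Klrb1c, 1 of 4 members (1 adjusted over the list alone, adjusted p = 1.87e-06, and adjusted p = 0.0784 estimated). The list of IL-2 and STAT5 targets did not pass, with 4 of 49 higher and 7 lower (6 and 8 adjusted over the list alone, mean -0.03, adjusted p = 0.18). In all, 720 genes rose and 683 fell by edgeR, against 848 in total by DESeq2 and 849 without CD8 gut anti-IL-2 replicate 2, and 149 genes rose and 152 fell in each of the 4 populations of these batches. In batch 190306 the mean difference was -1.19 for follicular helper genes, -0.53 for interferon response genes, -0.63 for inhibitory receptor genes, -1.46 for stroma markers and -0.30 for epithelium markers. For proliferation genes it was 0.48.

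Differences between treatment effects were tested directly, with libraries of the same batch and treatment taken as independent. With all batches, 0 genes passed in the 4 interactions by edgeR (437, 497, 40 and 216 at an unadjusted p under 0.05), while DESeq2 called 3, 0, 0 and 0 and limma voom 0 in each. In batches 181201 and 181212 the treatment effect differed between gut and spleen for 451 genes upward and 254 downward in CD4 cells, and for 173 and 140 in CD8 cells. Between CD4 and CD8 cells it differed for 22 and 98 genes in spleen and for 3 and 8 in gut. Gzmb differed between the tissues in CD4 cells by 1.84 ± 0.16, with an effect of 0.16 in gut and -1.67 in spleen. For proliferation genes the treatment effect was higher in gut than in spleen for 33 of 40 members in CD4 cells (38 adjusted over the list alone, adjusted p = 3.56e-52, and adjusted p = 0.142 with an estimated correlation). The same held for 21 in CD8 cells (35 adjusted over the list alone, adjusted p = 6.78e-45, and adjusted p = 0.184 estimated). Cytotoxicity genes differed in the same direction in CD4 cells, with 12 of 19 higher and 1 lower (13 and 2 adjusted over the list alone, adjusted p = 7.82e-14, and adjusted p = 0.127 estimated). Foxp3 differed between CD4 and CD8 cells of the spleen by 3.38 ± 0.41, and Klrb1c by 2.33 ± 0.18 in spleen and 2.38 ± 0.22 in gut. Deptor differed by -2.25 ± 0.43 in spleen and -3.63 ± 0.34 in gut. Without the batch term the counts of interaction genes fell to 230, 66, 52 and 1.

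Gut T cells were compared with spleen T cells of the same cell type and labelled treatment, to ask how tissue shapes donor T cells. All 3 batches were used, so the batch with the opposite treatment difference was kept. That batch makes up more of the gut IgG than of the spleen IgG libraries, so its difference can enter the IgG values. For Il2ra these were -0.45 in CD4 and -0.22 in CD8 cells, but 0.24 and 0.46 with a block of batch by treatment. None of these passed. If treatment labels were exchanged in that batch, each comparison mixes treatments. In each of the 4 comparisons gut cells held more RNA of the integrin chain Itgae (CD103, which binds epithelial E-cadherin), with log2 fold changes of 3.10 ± 0.61 in CD4 IgG, 4.07 ± 0.60 in CD4 anti-IL-2, 5.73 ± 0.71 in CD8 IgG and 6.51 ± 0.68 in CD8 anti-IL-2 cells. Pmepa1, Smad7 and Skil, feedback regulators of TGF-beta signalling, were higher as well, Pmepa1 by 4.87 ± 0.53, 5.28 ± 0.50, 6.89 ± 0.61 and 7.36 ± 0.61 in the same order. Further rises were those of Apol9b, from 5.09 in CD4 IgG to 9.15 in CD8 anti-IL-2 cells, and of Ppp2r2c and Osgin1. Rgs1, a regulator of chemokine receptor signalling, was higher by 3.84 ± 0.59 in CD4 IgG and 3.83 ± 0.59 in CD8 IgG cells. Cish was higher by 2.52 ± 0.61 in CD4 anti-IL-2, 3.41 ± 0.65 in CD8 anti-IL-2 and 2.34 in CD8 IgG cells. In CD4 IgG cells it was at 1.81 and did not pass. With a block of batch by treatment Cish passed in each of the 4 comparisons, at 2.40 to 3.38. Ifng, the Th1 cytokine, was higher by 1.99 ± 0.39 in CD4 IgG, 1.41 in CD4 anti-IL-2 and 1.90 ± 0.39 in CD8 IgG cells. Lower transcripts included Slc40a1 in CD4 cells (-6.76 ± 2.17 with IgG and -6.19 ± 1.57 with anti-IL-2). Slc40a1 is also made by macrophages, and RNA of spleen macrophages was not separated from that of T cells. In CD8 cells Tmprss13 (-1.95 ± 0.29 and -2.09 ± 0.24) and Cmah, a sialic acid hydroxylase (-1.41 ± 0.17 and -1.74 ± 0.15), were lower, in the same order of treatments. Il2ra, Il2rb, Socs2, Tcf7 and Tox did not pass in any of the 4 comparisons of this model, which has no block of batch by treatment. With a block of batch by treatment Tox was lower in each, at -0.60 ± 0.12, -0.45 ± 0.10, -0.60 ± 0.12 and -0.70 ± 0.10 in the same order. Tcf7 was lower in CD4 IgG (-1.27 ± 0.41), CD4 anti-IL-2 (-1.85 ± 0.35) and CD8 anti-IL-2 cells (-1.14 ± 0.34), and Socs2 higher in CD4 anti-IL-2 (1.51 ± 0.35), CD8 IgG (1.31 ± 0.44) and CD8 anti-IL-2 cells (2.37 ± 0.42). Il2rb passed in CD8 anti-IL-2 cells (-0.24 ± 0.08) and Il2ra in none, with 0.0537 as its smallest adjusted p.

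**Figure D4:**
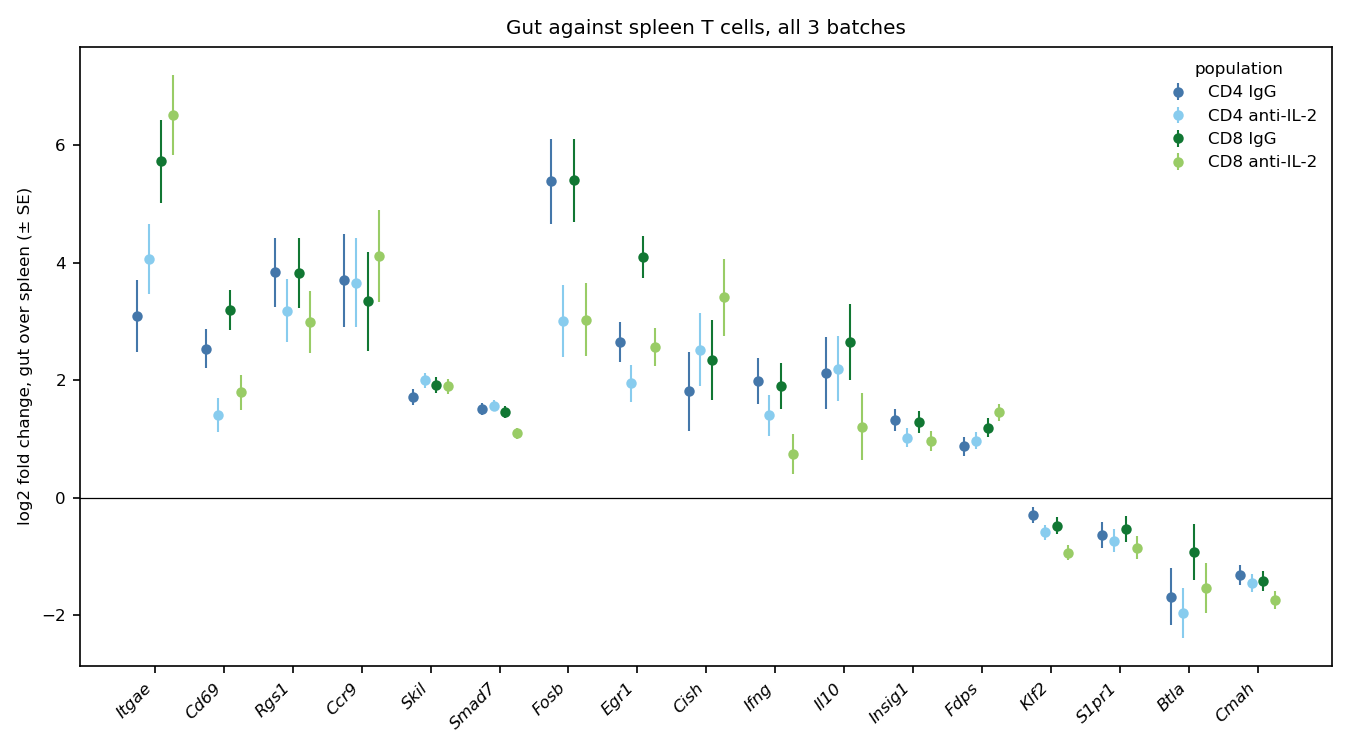
Log2 fold change of gut over spleen T cells (vertical axis) with its standard error for 17 genes (horizontal axis) in each cell type and treatment, from the edgeR model of all 3 batches. Itgae lies between 3.10 and 6.51 and Cmah between -1.74 and -1.32.

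Gene lists separated gut from spleen in each comparison. The counts given here and in the next paragraph are of members in the direction named, and members that went the other way are not counted. Tissue residence and gut homing genes were higher in 10, 9, 7 and 8 of 16 members in CD4 IgG, CD4 anti-IL-2, CD8 IgG and CD8 anti-IL-2 cells (10, 12, 10 and 11 adjusted over the list alone). Their adjusted p was 3.98e-07, 1.49e-07, 5.94e-07 and 1.34e-07, and 0.0112, 0.0039, 0.0165 and 0.00773 with an estimated correlation. The list of retinoic acid, TGF-beta and gut environment genes, which shares Itgae and Ccr9 with it, passed both ways too, with 8, 8, 7 and 7 of 16 higher (9, 9, 7 and 9 adjusted over the list alone). The adjusted p was 0.00245, 0.000449, 0.00283 and 0.00148 with an estimated correlation. Th1 and inflammatory genes were higher in 6, 8, 5 and 4 of 21 members (7, 9, 6 and 7 adjusted over the list alone), such as Ccl3 (2.02 ± 0.27 in CD4 anti-IL-2 cells) and Tnf (2.83 ± 0.28 in CD8 IgG cells). This call held with an estimated correlation except in CD8 anti-IL-2 cells (adjusted p = 0.0958). Stress and immediate early genes were higher in 16, 13, 16 and 11 of 25 (19, 14, 17 and 14 adjusted over the list alone), with Egr1, an immediate early transcription factor, at 4.10 ± 0.36 in CD8 IgG cells. Their adjusted p rose to 0.127, 0.268, 0.108 and 0.342 with an estimated correlation. Cholesterol synthesis genes were higher in 14, 16, 15 and 17 of 23 (17, 18, 15 and 18 adjusted over the list alone), such as Fdps, which makes farnesyl diphosphate (1.45 ± 0.15 in CD8 anti-IL-2 cells). Their adjusted p was 0.248, 0.124, 0.232 and 0.0958 estimated. The list of IL-2 and STAT5 targets was higher in 14, 18, 13 and 12 of 49 members (18, 23, 14 and 13 adjusted over the list alone). Some members may have been lower, as Bcl2 was in CD4 anti-IL-2 cells (-0.86). The adjusted p was 0.000817, 0.000278, 0.000698 and 0.00292, and 0.328, 0.255, 0.303 and 0.384 estimated. The member with the smallest p was Ecm1 in CD4 cells (1.86 ± 0.25 with IgG) and Ikzf4 in CD8 cells (2.44 ± 0.44 with IgG).

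Other lists differed in some of the comparisons. Proliferation genes were lower in 31 of 40 members in CD8 IgG gut cells (38 adjusted over the list alone, adjusted p = 3.81e-16, and 0.293 with an estimated correlation), with Mki67 at -1.07 ± 0.28. In CD4 IgG cells 0 of 40 passed and the list was called down (adjusted p = 0.000949, and 0.668 estimated). Th17 genes were higher in CD4 cells, 5 of 10 with either treatment (7 with IgG and 5 with anti-IL-2 adjusted over the list alone, and adjusted p = 0.328 and 0.321 estimated), led by Il17a (5.63 ± 0.85 and 5.57 ± 0.82). Follicular helper genes were lower in CD4 anti-IL-2 cells, 4 of 13 (7 adjusted over the list alone, and adjusted p = 0.427 estimated), with Btla, an inhibitory receptor, at -1.96 ± 0.42. So were naive and memory genes, 4 of 18 (4 adjusted over the list alone, and adjusted p = 0.141 estimated). Klf2, a regulator of tissue exit, was at -0.59 ± 0.13 and -0.93 ± 0.13 in CD4 and CD8 anti-IL-2 cells. Markers of colon epithelium were higher in 5, 16, 9 and 18 of 23 members (6, 18, 11 and 21 adjusted over the list alone). Their adjusted p was 0.000874, 6.64e-10, 5.98e-06 and 8.75e-15, and 0.411, 0.124, 0.293 and 0.0958 estimated. Their summed level ran from 38.7 to 351 CPM in gut libraries and from 19.9 to 30.0 CPM in spleen libraries. In all, 1148 genes were higher and 949 lower in CD4 IgG, 1422 and 1063 in CD4 anti-IL-2, 1293 and 1104 in CD8 IgG, and 1290 and 1001 in CD8 anti-IL-2 cells. Of these, 485 genes were higher and 319 lower in each of the 4. Without the batch term the totals fell to 775, 1083, 877 and 791, and without batch 181201 to 1062, 594, 1092 and 763. Without batch 190306 they were 3587, 4383, 3200 and 3766, and with a block of batch by treatment 3774, 4436, 3831 and 4137. The CD4 IgG total was 1365 without CD4 spleen IgG replicate 2 and 817 without CD4 gut IgG replicate 1. The CD4 anti-IL-2 total was 1383 and 1458 without CD4 spleen anti-IL-2 replicates 1 and 2. The CD8 IgG total was 1410 without CD8 spleen IgG replicate 2 and 1353 and 1041 without CD8 gut IgG replicates 1 and 2. The CD8 anti-IL-2 total was 1337 without CD8 spleen anti-IL-2 replicate 2 and 1397 without CD8 gut anti-IL-2 replicate 2.

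CD4 and CD8 libraries carried the markers they were sorted by. Cd4 was at 2158 ± 210 CPM (SD, n = 11) in CD4 cells and 2.25 ± 1.88 CPM in CD8 cells, and Cd8a at 1460 ± 432 CPM in CD8 cells. Averaged over tissues and treatments in all batches, the log2 fold change of CD4 over CD8 cells was 9.99 ± 0.32 for Cd4, 5.79 ± 0.13 for the helper ligand Cd40lg and 5.23 ± 0.30 for the chemokine receptor Ccr4. It was -10.15 ± 0.29 for Cd8a, -6.65 ± 0.07 for Cd8b1 and -3.71 ± 0.21 for the receptor gene Cd244. Th2 genes were higher in CD4 cells in 10 of 10 members (10 adjusted over the list alone, adjusted p = 1.82e-13, and 0.0226 estimated). Regulatory T cell genes were higher in 14 of 20 (14 adjusted over the list alone, adjusted p = 6.79e-08, and 0.00366 estimated). Proliferation genes were lower in CD4 cells in 40 of 40 (40 adjusted over the list alone, adjusted p = 8.77e-25, and 0.19 estimated). Cytotoxicity genes were lower in 15 of 19 with 2 higher (the same adjusted over the list alone, adjusted p = 2.97e-06, and 0.19 estimated). In all, 3408 genes were higher and 3486 lower by edgeR. By the annotation of build mm10, Il2ra lies on chromosome 2 at 11642807 to 11693193 and Socs2 on chromosome 10 at 95385362 to 95417180. Cish lies on chromosome 9 at 107296026 to 107302784, Tcf7 on chromosome 11 at 52252371 to 52283014 and Itgae on chromosome 11 at 73090583 to 73147446, each as a protein-coding gene.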

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

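The tests of batch 190306, of the tissue names of the CD8 IgG libraries, of RNA from other cells and stress in the gut libraries, and the counts over other splits of the libraries were chosen only after the results were seen, as was the fit of batches 181201 and 181212.

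The labelled treatment difference was tested against batch, and it differed in batch 190306 for 3123 genes in spleen CD4, 2070 in spleen CD8, 1921 in gut CD4 and 1666 in gut CD8 cells. In that test each group of batch 190306 held 1 library, so the spread came from the other batches alone. On a scale with the IgG libraries of the other batches at 0 and their anti-IL-2 libraries at 1, the IgG libraries of batch 190306 lay at 0.836, 0.840, 0.447 and 0.421, and its anti-IL-2 libraries at 0.0262, -0.0240, 0.0374 and 0.00973, in the same order. So 6 of its 8 libraries lay nearer the other label, and an exchange of treatment labels in that batch may be the cause. The 2 gut IgG libraries lay nearer their own label, with 0.421 as the lowest. But the gut scale has a single IgG library in the other batches, and genes with larger differences weigh more on it. Genes of other tissues, such as Cpb1, were among the largest rises in gut, and their part in these positions was not tested. So the test cannot tell an exchange of labels from an opposite response. An opposite response of rightly labelled animals would put the anti-IL-2 libraries far below 0, where none lay, and it stays open only together with a shift of the whole batch along the scale, which was not tested, so directions of treatment refer to libraries labelled anti-IL-2.

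For 5 CD8 IgG libraries the description names the other tissue than the source name. On 200 genes that separate gut and spleen in the remaining libraries, 0 of the 5 libraries lay nearer the tissue of the description, which argues against that field as the right one. The lowest gut score among the 5 was 0.56, and the highest spleen score was -0.55. How the names came to differ stays open, and no biological explanation was tested.

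Genes higher in gut than in spleen T cells may include RNA carried over from colon epithelium, although the sort for donor T cells would remove whole epithelial cells. Only epithelium was tested as a source. Markers of B and plasma cells had a mean log2 CPM of 1.78 to 2.29 in gut groups and 0.71 to 1.39 in spleen groups. Carry-over from those cells, stroma, fat or pancreas was not tested. Over 2342 of the genes higher in at least 1 gut comparison, the log2 shift among the 10 gut libraries changed by 0.0431 (95% interval 0.00319 to 0.0829) per doubling of 28 summed epithelium markers, where carry-over as the whole cause would need at least 0.350 in CD4 and 0.288 in CD8 cells. Across libraries the shift had r = 0.699 with the markers (permutation p = 0.0113, Spearman permutation p = 0.0730, and r = 0.463 without the 2 farthest libraries). But r was -0.245 (permutation p = 0.501) over 470 of the 485 genes higher in all 4 comparisons, with listed epithelium and stress genes left out. Carry-over from epithelium is therefore argued against only as the whole cause and stays open as a part. For a stress response in proportion to the level of the stress list the slope was -0.00803 (-0.104 to 0.0875) per log2 unit, where 0.489 and 0.475 would be needed, which argues against it as the whole cause. The intervals take the libraries as independent, and a stress response already at its full size in each gut library, and an effect of the gut on T cells, stay open and untested.

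In batches 181201 and 181212 the treatment effect differed between gut and spleen for 705 genes in CD4 and 313 in CD8 cells, and between cell types for 120 genes in spleen and 11 in gut, by a test of the difference itself. Each of these fits holds 1 IgG library per gut group, and takes libraries of the same batch and treatment as independent. RNA of other cells in the gut anti-IL-2 libraries could give some of these differences, which was not tested. The epithelium marker Epcam, for one, had an effect of 1.97 in gut CD8 and 0.24 in spleen CD8 cells. In CD4 cells the log2 difference of gut from spleen was 3.48 for Pls1, 2.38 for Miat, 2.23 for Ermn, 2.16 for Mybl1 and 1.84 for Gzmb, and -2.30 for Ssbp2, -1.95 for Tmem230, -1.87 for Itga7, -1.86 for Wbscr27 and -1.83 for Cacna1d. In CD8 cells it was 2.08 for Nid2, 1.85 for Gzma, 1.79 for Muc20, 1.73 for Cd244 and 1.73 for Epcam, and -2.35 for Apol8, -2.11 for Egr1, -1.89 for Rgs10, -1.88 for Tmem230 and -1.62 for Tnf. The difference of CD4 from CD8 cells in spleen was 3.38 for Foxp3, 2.77 for St6gal1, 2.48 for Esm1, 2.33 for Klrb1c and 1.91 for Nid2, and -2.28 for Flt1, -2.25 for Deptor, -2.10 for Ccr6, -1.96 for Ccr9 and -1.93 for Csf2. In gut it was 2.38 for Klrb1c, 1.28 for Mx1 and 1 for Crim1, and -3.63 for Deptor, -1.90 for Ccr9, -1.63 for Map6, -1.07 for Mns1 and -0.84 for Swap70.

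Other splits of the same libraries were counted for comparisons of 3 libraries or more per group. For gut against spleen in anti-IL-2 cells the real split called 2485 genes in CD4 and 2291 in CD8 cells, with 0 as the highest of the others, and 1 of 10 splits reached the real count, too few splits for a share under 0.05. For anti-IL-2 against IgG in spleen CD4 cells the real split called 0 genes by edgeR (282 at an unadjusted p under 0.05, and 0 by DESeq2 and limma voom) and the highest other 701. With a real count of 0, 10 of 10 splits reach it by construction, here and in the next comparisons with 0, so that share tests nothing. The split with 701 genes exchanges the 2 libraries of batch 190306, which points to a structure of the samples by that batch, and with these 6 libraries alone it called 2841 genes. In spleen CD8 cells the real split and the highest other called 0 (148 at an unadjusted p under 0.05, and 0 by DESeq2 and limma voom), and with the 6 libraries alone the same exchange called 2319. Without batch 190306 the counts were 2627 and 1587. For the treatment effect between cell types in spleen both counts were 0 (40 at an unadjusted p under 0.05, and 0 by DESeq2 and limma voom). These comparisons, too, have too few splits for a share under 0.05. For CD4 against CD8 cells 40 splits were drawn from a larger number of possible exchanges, the real split included. Of these, 1 of 40 reached the 6894 genes of the real split, and the highest other called 3. The sort had already set these groups apart, so this shows only that the sort labels track expression.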

How the results depend on the processing

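Leaving out batch 190306, and the alternatives for batches 181201 and 181212, were chosen only after the results were seen. Where no cause is named, the cause was not tested.

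With all batches, anti-IL-2 against IgG kept 0 genes by edgeR in each population (282, 148, 750 and 953 at an unadjusted p under 0.05) under most alternatives. The exceptions were 8 genes in gut CD4 and 18 in gut CD8 cells by DESeq2, 1 in gut CD4 with RLE factors, 1 in gut CD8 by limma voom, and 2 and 1 in gut CD4 without CD4 gut anti-IL-2 replicate 2 and without CD4 gut IgG replicate 2. Leaving out 1 library gave 0 to 2 in gut CD4 cells and 0 in the other populations. The treatment effect differed by tissue for 3 genes in CD4 cells by DESeq2, and for 1 in CD4 and 5 in CD8 cells with a block of batch by treatment. Without batch 190306 the treatment counts were 2627, 1587, 1533 and 1403, and the interaction counts 705, 313, 120 and 11.

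Gut against spleen called 2097, 2485, 2397 and 2291 genes. The counts were 775, 1083, 877 and 791 without the batch term, 1062, 594, 1092 and 763 without batch 181201 (fewer libraries), 746, 1137, 1490 and 1500 with libraries of the same cell type only (fewer libraries), and 3774, 4436, 3831 and 4137 with a block of batch by treatment. By limma voom the anti-IL-2 counts were 5105 in CD4 and 4132 in CD8 cells, and without batch 190306 the counts of CD4 IgG, CD4 anti-IL-2 and CD8 anti-IL-2 were 3587, 4383 and 3766. Leaving out 1 library gave 817 to 1654, 1383 to 2739, 1041 to 1941 and 1337 to 1734. CD4 against CD8 stayed within 1.5-fold of 6894 under each alternative run, and at 6380 to 6933 when 1 library was left out.

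With the tissue of the description for the CD8 IgG libraries, anti-IL-2 against IgG called 2212 genes in spleen CD8 and 2540 in gut CD8 cells, the interactions called 4502 by tissue in CD8 cells and 786 and 943 by cell type in spleen and gut, and the list of IL-2 and STAT5 targets moved to -0.549 (adjusted p = 0.000479) in spleen CD8 and, reversed, to 0.430 (adjusted p = 0.00496) in gut CD8 cells. By construction this setting sets gut against spleen libraries, and it exchanges gut and spleen in CD8 IgG cells, with 1104 genes higher and 1293 lower instead of 1293 and 1104.

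The list of IL-2 and STAT5 targets passed without batch 190306 in spleen CD4 (mean -0.177, adjusted p = 0.000244) and spleen CD8 cells (-0.128, adjusted p = 0.0449). These calls were lost with an estimated correlation (adjusted p = 0.254 and 0.671), and in spleen CD8 cells with no filter (-0.102, adjusted p = 0.634), the stricter filter (-0.123, adjusted p = 0.0793) and limma voom (-0.119, adjusted p = 0.473). With all batches, leaving out 1 library gave means of -0.146 to 0.033 in spleen CD4, -0.140 to 0.064 in spleen CD8, -0.088 to 0.089 in gut CD4 and -0.180 to 0.060 in gut CD8 cells. The list then passed without CD4 spleen IgG replicate 3 (-0.146), CD8 spleen IgG replicate 3 (-0.140), CD8 gut IgG replicate 1 (-0.039) and CD8 gut anti-IL-2 replicate 3 (-0.180). In batches 181201 and 181212 the means ran from -0.268 to -0.060, -0.206 to -0.022, -0.098 to 0.096 and -0.065 to -0.027, and the spleen CD8 call was lost without CD8 spleen IgG replicate 1 (-0.022) and anti-IL-2 replicates 1 (-0.120) and 2 (-0.143).

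In batches 181201 and 181212, DESeq2 called 1036 genes in spleen CD8, 946 in gut CD4 and 848 in gut CD8 cells, and 28 for the interaction by cell type in gut, where no filter gave 36. Without the batch term gut CD4 gave 872 and the interactions 230, 66, 52 and 1. Leaving out 1 library gave 1562 to 1882, 669 to 954, 635 to 857 and 849 to 1030, with a lone library taken to vary like the other groups. In simulated counts at these depths a 2-fold change was recovered for 82% of changed genes in the spleen CD4 treatment contrast of all batches. In batches 181201 and 181212 it was recovered for 94%. The simulation held no batch effect and no opposite batch, and what depth itself limits was not tested. Single genes were not run with the tissue of the description. They were also not compared between the fit of all batches and the fit of batches 181201 and 181212, so this check cannot show reversals between these fits. Under the other alternatives, within each fit, none that was called reversed. Over single genes, comparisons and alternatives, 269 calls were lost and 68 gained with all batches and 109 and 12 in batches 181201 and 181212, while leaving out 1 library lost 250 and 87 and gained 9 and 8.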

Other observations

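Markers of neutrophils were higher in spleen libraries labelled anti-IL-2 in 2 of 3 batches. Their mean difference in log2 CPM in batches 181201, 181212 and 190306 was 1.23, -0.65 and 3.96 in spleen CD4 cells, and 1.67, -0.96 and 3.69 in spleen CD8 cells. Proliferation genes were at 0.25 and 0.15 in gut CD4 cells of batches 181212 and 190306, and at 0.16 and 0.48 in gut CD8 cells, the same sign in both batches.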
